A study of Homo sapiens with 2 samples.

How the data were processed

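CRTC2, a coactivator of the transcription factor CREB, was immunoprecipitated together with its associated RNA (RNA immunoprecipitation sequencing, RIP-seq) from HCCLM3, an established human hepatocellular carcinoma cell line of unmodified genotype. The series holds 1 CRTC2 RIP library and 1 input library, the RNA taken before precipitation, with no replicate of either. It holds no precipitation with a control antibody. Per the labels' protocols, RNA was recovered with a Magna RIP kit and libraries were prepared with a stranded total RNA kit for low input. Per the submitters' processing notes, HISAT2 and MACS2 were used with hg38; their versions and settings are not given in the sources used here.

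The deposited data are a list of 175546 annotated peaks on 146 chromosomes and contigs, with no position listed more than once. For each peak the authors deposited a fold enrichment, which is a linear ratio of RIP over control at the summit and is treated here as RIP over the input library. The deposited list gives the −log10 p and the −log10 q of each peak in a pair of columns whose headers were spoiled before deposit and which were identified by their place and values. The deposited score of each peak equals 10 times the −log10 p rounded down for 100% of peaks and was not analysed further. Peak width, summit and distance to the nearest transcription start site are also the authors' values, per the file headers. The lowest −log10 p was 1.30, so the list holds every peak at an unadjusted p of about 0.05, and −log10 q was 0 for 88.8% of peaks. All fold, p and q values are the authors' and serve here only to describe and rank peaks within this list.

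The number of RIP fragments at each summit and the local input level were recovered from the fold and the −log10 p. With a pseudocount of 1, the fold equals the fragments plus 1 over the input level plus 1, and the p is a Poisson tail. A whole number of fragments met both values within 0.001 for 100% of peaks, against 3.96% after the p-values were shuffled among peaks. A single number met them for 97.5% of peaks; for the others the closest was taken. The recovered input levels fell on a grid. They lay at a floor of 0.0298 for 10.3% of peaks and at whole multiples of 0.634 for 36.4%. Of the other input levels, 99.999% lay on the steps that a fragment length of 31 bp gives in windows of 1 kb and 10 kb, and lengths from 10 to 200 bp gave a median of 0.497%. A fragment below is therefore 1 read as the caller counted it, placed as 31 bp, and 1 input fragment counted as 0.634. If the caller assumed a genome of 2.7 Gb, a setting not given in the sources used here, the floor corresponds to 2.60 × 10⁶ RIP fragments and 4.10 × 10⁶ input fragments. Summits held a median of 2 RIP fragments (quartiles 1 and 4, at most 49), and 46.2% of peaks rested on 1 fragment. Intervals given with a fold are exact Poisson 95% intervals of the RIP fragments at the fixed input level, and intervals of shares are exact Clopper-Pearson 95% intervals. All cover counting error only.

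Regions are the annotation classes in the deposited list, where a peak within 3000 bp of a transcription start site is called promoter before any other class. An exon peak was counted for the gene named in its exon annotation, and a UTR peak for the assigned gene if it overlapped the assigned transcript. Such peaks are called exonic below. A peak in the promoter class is not counted as exonic, so a gene without an exonic peak may still have one there. The assigned gene, which is the one with the nearest start site, was also the exon's gene for 55.0% of 53302 exon peaks, and 47.9% of 27950 UTR peaks overlapped the assigned transcript. This assignment was chosen after those shares were seen. Of 19297 gene identifiers, 19279 matched a RefSeq gene table, which gave symbols, gene classes and lengths.

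Gene lists, the rule for named genes, the main measures and most alternatives were chosen before the data were examined. The rule named CRTC2 and YTHDF2, the 10 genes with the highest fold among exonic peaks with −log10 q above the median, the 10 with the highest −log10 q, the 5 with the most exonic peaks, and up to 4 members of each list with the highest fold, plus its members without a peak where these were 5 or fewer. That median was 0. Not every gene that the rule named is reported here. Other members named because they carry a peak at q of at most 0.05 were chosen after their values were seen. The q limit of 0.05, the limits of 5 fragments and 1 kb, and other gene assignments were also added after the data were seen.

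With 1 library per group no p-value across genes was computed and nothing here has a replicate check. The share of a list's members with an exonic peak was placed as a percentile among 10000 random lists of the same size, matched on gene class and gene length in 20 bins. The median over members of each gene's highest fold was placed among 10000 random lists of genes with an exonic peak, matched on the number of exonic peaks. This number was matched in coarse bins, the highest of them open-ended, and genes with as many peaks below are genes of the same bin. Matching on the median input level of each gene's exonic peaks, in 20 bins, was an alternative. A list counted as outside when its percentile was above 97.5 or below 2.5. Tested on simulated data, the recovery gave the right number of fragments for 99.97% of 18564 peaks. Among 100 simulated lists of 30 genes, 2% without an effect and 98% with folds raised 1.3-fold lay above the upper limit for fold, and 4% without and 87% with peaks added to 50% of members for coverage. Of 15 mitochondrially encoded genes 1 was in the gene table, so this list is void. No genome sequence or transcript model was used here, so motif density, distance to stop codons and overlap with exons were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.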

Results

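RNA precipitated with CRTC2 from HCCLM3 liver cancer cells was compared with input RNA, 1 library each, to find the transcripts that CRTC2 associates with. Without a control precipitation, RNA bound to CRTC2 cannot be told apart from RNA that the precipitation carried over. The series concerns joint condensates of CRTC2 and YTHDF2, a reader of N6-methyladenosine (m6A) in mRNA, and the fate of m6A-modified mRNAs. The list held 175546 peaks with a median fold of 1.89 (quartiles 1.76 and 2.35, at most 29.1) and a median width of 101 bp. A q of at most 0.05 was reached by 2859 peaks (1.63%), whose median fold was 4.50 on a median of 5 RIP fragments at the summit. No value below has a replicate, and folds are the authors' per-peak values.

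The CRTC2 transcript itself carried 6 exonic peaks and the YTHDF2 transcript 6, and no peak of either reached q of 0.05. The highest CRTC2 peak lay in exon 9 of 14 (hg38 chromosome 1, 153952008 to 153952414), with a fold of 3.73 (1.84 to 6.94) on 8 RIP fragments. The highest YTHDF2 peak lay in exon 5 of 6 (chromosome 1, 28742425 to 28742492), with a fold of 3.42 (1.75 to 6.18) on 9 fragments. The median fold over each gene's exonic peaks was 2.68 for CRTC2 and 2.61 for YTHDF2. The intervals of the highest peaks overlapped, and a difference between the transcripts was not tested.

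**Figure D1:**
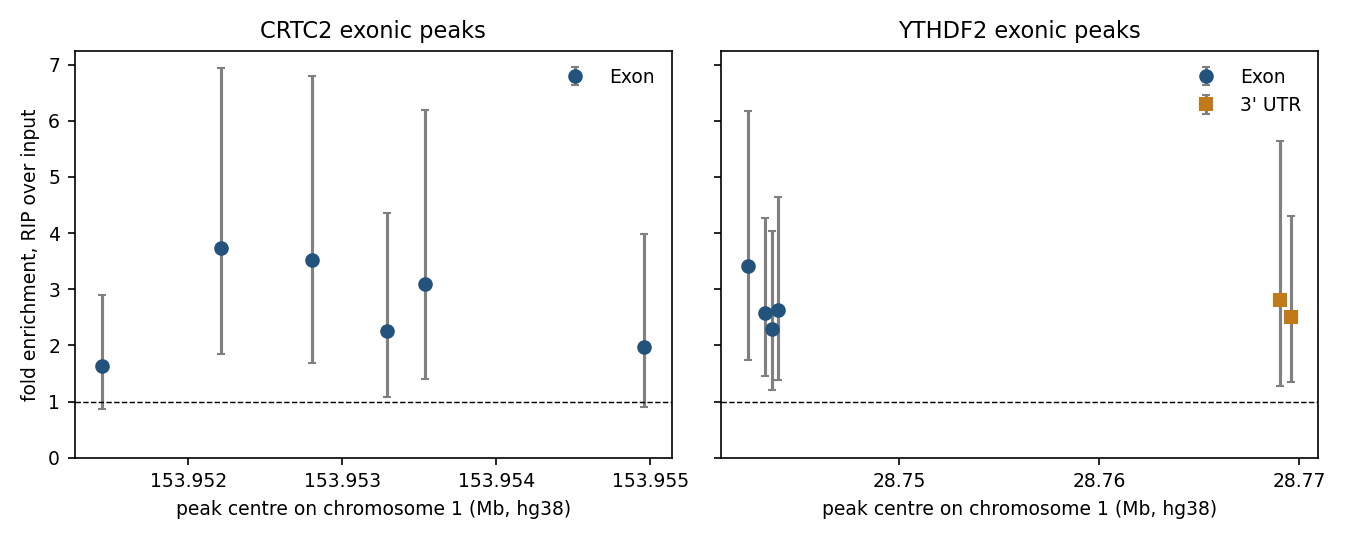
Fold enrichment of RIP over input (vertical axis) for each exonic peak of CRTC2 and YTHDF2 against the position of the peak's centre on chromosome 1 in Mb (hg38). Points are single peaks, circles in exons and squares in the 3′ UTR, bars are exact Poisson 95% intervals of the RIP fragments, and the dashed line is a fold of 1; the highest points are 3.73 for CRTC2 and 3.42 for YTHDF2.

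Exons held the largest share of peaks. Of all peaks, 30.4% (30.1 to 30.6) lay in exons, 26.6% in introns, 20.9% in promoters, 13.8% in 3′ UTRs, 6.09% in distal intergenic sequence, 2.08% in 5′ UTRs and 0.121% downstream of genes. Among the peaks at q of at most 0.05 the exon share was 55.6% (53.8 to 57.4) and the intron share 6.09% (5.24 to 7.03). The share of peaks that reached this q was 2.98% (2.84 to 3.13) in exons and 2.93% (2.41 to 3.54) in 5′ UTRs, against 0.926% (0.809 to 1.05) in 3′ UTRs and 0.372% (0.319 to 0.432) in introns. It was 1.77% in promoters and 1.08% in distal intergenic sequence, and 0 of 212 downstream peaks reached it.

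Median folds differed little between regions, from 1.80 downstream and 1.85 in introns to 1.94 in exons and 5′ UTRs. The depth behind them differed more. Exon summits held a median of 4 RIP fragments (quartiles 2 and 7) and 15.6% of exon peaks rested on 1 fragment. Intron summits held a median of 1, and 85.8% of intron peaks rested on 1 fragment. When each peak was weighted by its width, the exon share was 4.26%, because 16141 peaks wider than 10 kb held 2518 of 2596 Mb.

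**Figure D2:**
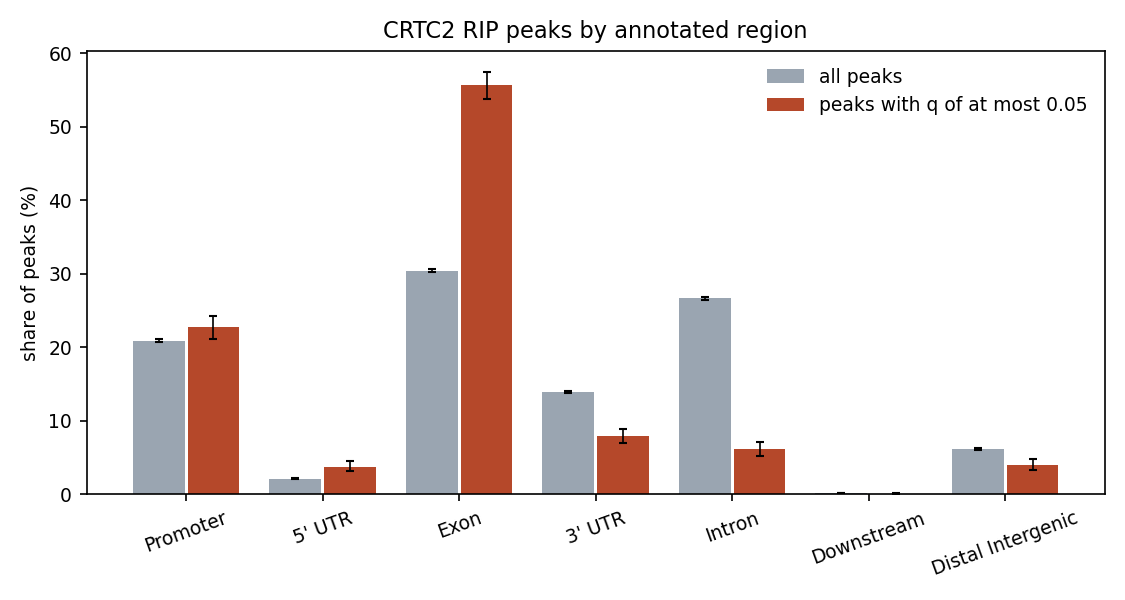
Share of peaks in percent (vertical axis) by annotated region (horizontal axis), for all 175546 peaks and for the 2859 peaks with q of at most 0.05. Bars are shares and lines exact 95% binomial intervals; exons hold 30.4% of all peaks and 55.6% of those at the q limit, introns 26.6% and 6.09%.

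An exonic peak was found in 10735 genes, among them 9876 of 20056 protein-coding genes (49.2%) and 640 long non-coding RNA genes. Among the 10 genes of highest fold was NAP1L4, a histone chaperone gene, with 12.7 (7.48 to 20.5) on 15 fragments in exon 10 of 16 (chromosome 11, 2958374 to 2958539). TAF1, the largest subunit of the general transcription factor TFIID, reached 10.4 (6.21 to 16.5) in exon 22 of 38 (chromosome X, 71394089 to 71394274), and 11 of its 32 exonic peaks were at q of at most 0.05. YTHDC1, the nuclear m6A reader, reached 10.03 (5.43 to 17.3) in exon 3 of 17 (chromosome 4, 68337546 to 68337854). The transcription factor gene NFKB1 reached 8.50 (4.35 to 15.4) in exon 6 of 24, with 4 of 18 exonic peaks at that q.

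Also among these 10 were NBPF19 (12.6, in a peak wider than 10 kb), ATAD3A (11.1), DLG5 (8.66), NBPF8 (8.60) and PHRF1 (8.34). NBPF19 and NBPF8 belong to a family of near-identical copies and ATAD3A has close paralogs, so their reads are of uncertain origin. The highest peaks of DLG5 and PHRF1 lay on alternative contigs. The ranking by q added RAB11FIP3 (7.77, on 7 fragments), a partner of endosomal RAB11, and INTS3 (7.70, on 7 fragments), a subunit of the Integrator complex. Their peaks were 4880 and 7266 bp wide, at input levels of 0.0298 and 0.0393, at or near the floor. The most exonic peaks were found in long transcripts. DST held 89, UBR4 80, MDN1 70, MACF1 67 and RNF213 65, and their highest folds lay between 4.36 in RNF213 and 6.12 in UBR4. A −log10 q of at least 5 was reached in 67 genes and a fold of at least 4 in 1453, against 1347 genes at q of at most 0.05.

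Genes of the m6A machinery and of CREB signalling carried peaks more often than random genes of their length, as did most lists (16 of 23 above the upper limit). At q of at most 0.05, 4 of 23 lists were above it. These were chromatin regulators, P-body and stress granule proteins, stress response genes and abundant non-coding RNAs. Matched on number of peaks, 0 of 21 lists were above it at this q. All 23 m6A writers, erasers and readers had an exonic peak, against a median of 60.9% in random lists, and all 10000 lists lay below. YTHDC1 (10.03-fold), the helicase-containing reader YTHDC2 (6.49), the demethylase FTO (4.93) and the writer subunit VIRMA (4.41) reached q of 0.05, and these 4 of 23 members lay within random lists (percentile 92.9). The m6A list's median fold lay at percentile 52.4 when matched on number of peaks. Of 22 CREB and CRTC signalling genes 21 had an exonic peak, all but the kinase subunit PRKACA, against a random median of 63.6%. Where exon and assigned gene agree it was 14 of 22 (percentile 88.5), and with all assigned peaks 22 of 22. CRTC3 (6.05-fold), the adenylyl cyclase ADCY9 (4.86, on 4 fragments at the lowest input level) and the phosphodiesterase PDE4D (4.72) reached q of 0.05. A peak of PRKAR1A below its highest fold of 3.84 also did, while PRKAA1 and SIK3 stood at 4.28 without it. The 4 of 22 members that reached this q lay within random lists (percentile 77.4). The median fold of the signalling list lay at percentile 90.6 when matched on number of peaks and at 98.1 when matched on input level.

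Of 20 CREB and CRTC target genes, 12 had an exonic peak (percentile 98.2, but 73.2 with at least 5 fragments and 82.5 in unmatched lists) and 0 reached q of 0.05. It was 18 of 20 with all assigned peaks (percentile 98.9) and 17 of 20 with the summit in the assigned transcript (99.9). The highest exonic peaks of IRS2, NR4A3, NR4A2, FOSB and PER1 rested on 1 fragment each. The highest folds were those of ATF3 (3.67-fold), CREM and SIK1 (3.53 each) and SALL1 (3.18), and CREM and SIK1 are also members of the signalling list. SIK1 is the deposited annotation's name for that peak (chromosome 21, 6122633 to 6122860), and the origin of its reads was not checked. The median of their highest folds, 2.99, lay at percentile 98.9 of random lists matched on number of peaks (random median 2.41) and at 69.1 when matched on input level. Of 20 widely studied m6A-modified mRNAs 15 had an exonic peak (percentile 99.2, but 95.2 where exon and assigned gene agree and 96.1 with all assigned peaks). HSPA1A, IL11, JUNB, SOCS2 and TNFRSF1B had no exonic peak, but with all assigned peaks 18 of 20 members had one. The protease inhibitor SERPINE2 (5.52-fold), EGFR (4.40) and NOTCH1 (3.78) reached q of 0.05. The median fold of these mRNAs lay at percentile 17.8. The random lists were drawn from all genes of like class and length, expressed in these cells or not, and expression was not used here.

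Liver cancer genes carried exonic peaks in 24 of 27 cases (percentile 99.96), with none in FGF19, GPC3 and TERT. With all assigned peaks 26 of 27 had one. AXIN1 (5.73-fold, 3.18 to 9.69), a scaffold of beta-catenin breakdown, the chromatin remodeller PBRM1 (4.83), the kinase RPS6KA3 (4.41), KMT2D (4.31) and TSC1 (3.78) reached q of 0.05. Of 36 lenvatinib targets and members of receptor tyrosine kinase, MAPK and PI3K signalling, 26 had a peak, or 72.2% against a random median of 61.1% (percentile 90.4). RICTOR, the defining subunit of mTOR complex mTORC2, stood out at 8.26-fold (4.23 to 14.9, exon 27 of 39) on 9 fragments. RPTOR (4.64, 1.94 to 10.4) and EGFR (4.40, 1.84 to 9.88) also reached q of 0.05, on 4 fragments each. PIK3R1 stood at 4.20 on 6 fragments. The median fold of this list, 2.78, lay at percentile 1.31 when matched on number of peaks and at 45.9 when matched on input level.

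Proteins of P-bodies and stress granules, the cytoplasmic RNA granules, had exonic peaks in 32 of 32 transcripts. Peaks at q of at most 0.05 lay in 9 of them, or 28.1% against a random median of 9.38% (3.13 to 21.9 in the central 95%, percentile 99.6), with TNRC6C (5.49-fold), PUM2 (5.10) and DDX6 (4.90) among them. Among genes with as many exonic peaks the list lay at percentile 68.0. Translation factors had a peak in 28 of 36 cases (percentile 99.9, but 97.1 where exon and assigned gene agree). EIF4G3 (6.09-fold), EIF3C (4.10, with a near-identical copy) and PABPC1 (2.78) reached q of 0.05, and EIF3D (3.79) and EIF2S1 (3.45) did not. Their median fold of 2.504 lay at percentile 0.62 when matched on number of peaks and at 94.2 when matched on input level. Splicing factors had an exonic peak in 30 of 35 cases, above all 10000 random lists. TRA2A (4.89-fold), SF3A1 (4.85) and CLK4 (4.72) were at q of at most 0.05, and CLK1 stood at 3.64. There was no exonic peak in DDX5, SRSF2, SRSF5, SRSF6 and U2AF1, but with all assigned peaks 33 of 35 members had one.

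Ribosomal protein genes had an exonic peak in 24 of 78 cases (30.8%, random median 24.4%, percentile 90.1). The highest folds included 3.67 for RPL34, 2.82 for RPS9 (on an alternative contig, 2 fragments) and 2.56 for RPS14. Replication-dependent histone genes had none in 23 (95% interval 0 to 14.8%). Peaks within 3000 bp of a start site are called promoter, which can take peaks of short genes out of the exon class. The classes of these genes' peaks were not counted here. With all assigned peaks, 77 of 78 ribosomal protein genes and 21 of 23 histone genes had one (percentile 100 for each list).

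Chromatin regulators had the largest share of members with a peak at q of at most 0.05. All 40 had an exonic peak, and 19 (47.5%) had one at q of at most 0.05, against a random median of 15% (5 to 25) and above all 10000 lists. The histone methyltransferase genes SETD5 (6.16-fold, 3.25 to 10.9), NSD1 (6.12), KMT2C (5.92) and KMT2B (5.51) were highest. These transcripts also carried many peaks, a median of 20 against 4 per gene with a peak. Among genes of the same bins of peak number, the highest of them open-ended, the list lay at percentile 77.7. Unfolded protein and stress response genes had a peak in 17 of 26 cases (percentile 99.2, but 94.4 in unmatched lists). Of these PDIA4 (4.85-fold), the stress sensors ERN1 (4.72) and ATF6 (3.78), and HERPUD1 (4.28) reached q of 0.05, or 15.4% against 3.85% (percentile 98.0, and 88.0 among genes with as many peaks).

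**Figure D3:**
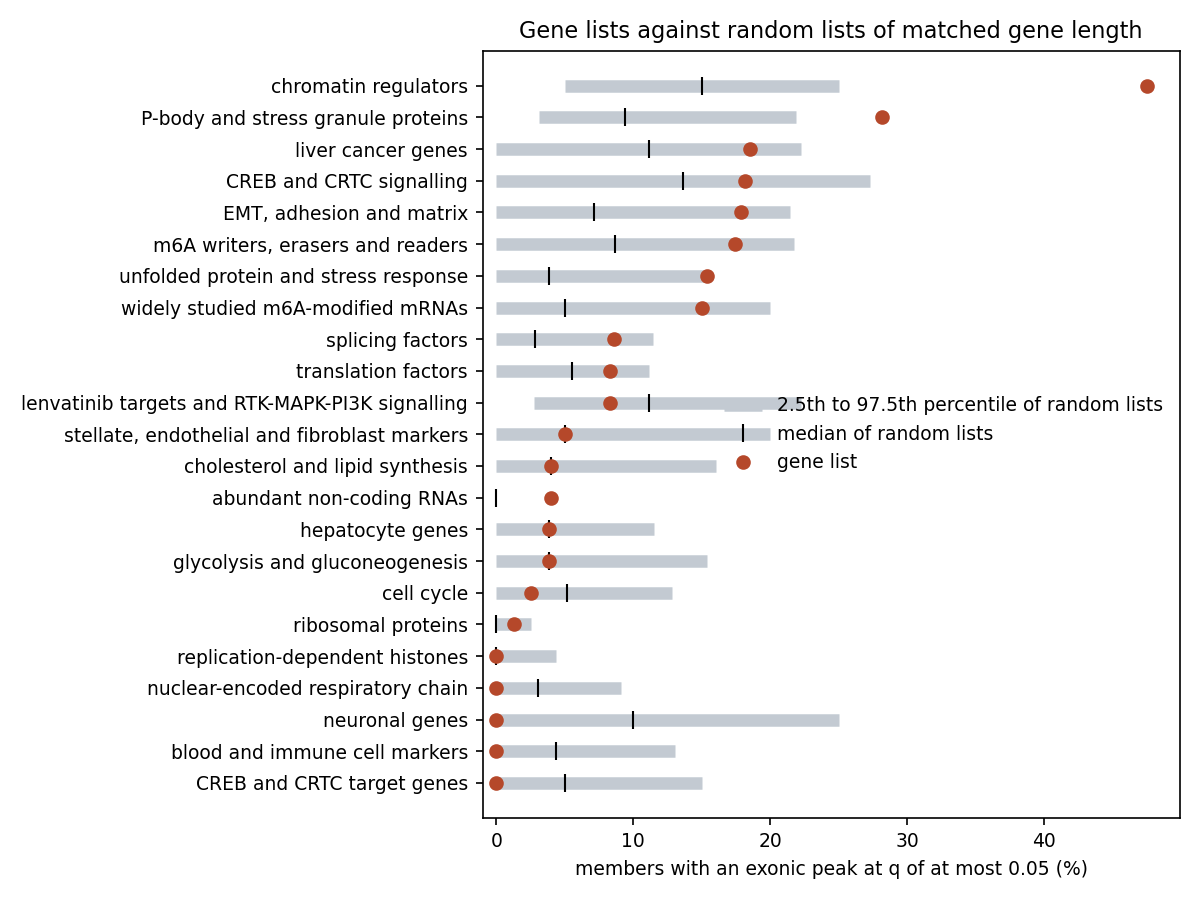
Share of each gene list's members with an exonic peak at q of at most 0.05, in percent (horizontal axis), for 23 lists (vertical axis). Circles are the lists, ticks the median and grey bars the central 95% of 10000 random lists matched on gene class and length; chromatin regulators (47.5%), P-body and stress granule proteins (28.1%) and abundant non-coding RNAs (4%) lie to the right of their bars.

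Genes of cholesterol synthesis, glycolysis and the respiratory chain often carried exonic peaks. All 25 cholesterol and lipid synthesis genes had an exonic peak, above all 10000 random lists, but only ACACA (4.86-fold, in a peak wider than 10 kb on an alternative contig, 4 fragments) reached q of 0.05; DHCR7 and SREBF2 stood at 3.67. Glycolysis and gluconeogenesis genes had a peak in 19 of 26 cases (percentile 98.8, but 92.3 where exon and assigned gene agree and 96.3 with all assigned peaks). PFKFB3, which makes the activator of phosphofructokinase, reached 6.12-fold (3.13 to 11.1) in its 5′ UTR and q of 0.05, and SLC2A1 (3.53), ENO2 (3.31) and HK1 (3.12) did not. The median fold of the glycolysis list, 2.21, lay below all 10000 random lists matched on number of peaks (random median 3.06), and at percentile 15.9 when matched on input level. Nuclear-encoded respiratory chain genes had a peak in 22 of 33 cases, above all random lists, with 0 at q of 0.05 and COX6C (4.28), SDHB (3.79), NDUFS1 (3.12) and NDUFA1 (3.11) highest. Cell cycle genes had an exonic peak in 35 of 39, above all random lists and with none in CCND2, CDC20, CDK2 and CDK4. With all assigned peaks 37 of 39 had one. Of the cell cycle genes E2F3 (4.14) reached q of 0.05, and BUB1 (4.28), E2F2 (4.25) and CDC25A (3.97) did not.

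Genes of EMT, adhesion and matrix had a peak in 21 of 28 cases (percentile 99.0, but 90.4 with at least 5 fragments and 67.5 where exon and assigned gene agree). The laminin chains LAMA5 (5.33-fold), LAMB1 (4.85) and LAMC1 (4.78), the receptor TGFBR1 (4.90) and N-cadherin, CDH2 (4.55), reached q of 0.05. Hepatocyte genes had one in 9 of 26 (percentile 29.7). APOB (3.88, on 3 fragments at the lowest input level) reached q of 0.05, and FOXA1 (3.36) and APOH (3.04) did not. Of 25 abundant non-coding RNAs 9 had a peak, above all random lists, with the highest folds in NEAT1 (3.90), OIP5-AS1 (3.06), TUG1 (3.02) and NORAD (3.01, on 23 fragments), of which NORAD reached q of 0.05 (4% of the list, percentile 99.2, and 49.4 among genes with as many peaks). Markers of other cell types lay below random lists. Blood and immune markers had a peak in 1 of 23 (ITGAM, 2.91-fold, percentile 0.015), stellate, endothelial and fibroblast markers in 3 of 20 (PECAM1 at 3.88, LUM at 2.49 and LYVE1 at 1.94, below all random lists), and neuronal genes in 3 of 20 (MAP2 at 3.92, TUBB3 at 3.45 and SYT1 at 2.45, percentile 0.015). PECAM1 reached q of 0.05, but its peak and that of ITGAM were wider than 10 kb, with 3 and 2 fragments at the lowest input level. On the mitochondrial genome there were 14 peaks and 0 at q of 0.05.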

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

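The limits q of at most 0.05, 5 fragments and 1 kb, and the assignments by matching exon gene or by summit, were chosen after the data were seen; the other alternatives here were chosen before. The number of peaks (175546) was 160 at −log10 q of at least 5, 2867 at a fold of at least 4, 2859 at q of at most 0.05 and 41005 with at least 5 fragments. It was within 1.5 times of the full list at a width of at most 1 kb (145775), and merging peaks within 100 bp left it at 175546, since the smallest gap was 151 bp. In the same order of limits, genes with an exonic peak (10735) numbered 67, 1453, 1347 and 6336, and 19297 with all assigned peaks. The exon share (30.4%) was 41.9%, 59.0%, 55.6% and 55.4%, and 33.5% up to 1 kb, 4.26% weighted by width and 38.4% without promoters. The median exon fold (1.94) was 6.86, 4.55, 4.63 and 2.07, and 1.98 up to 1 kb and 2.76 over each gene's highest peak. Shifts under limits on q, fold and fragments follow from the limits, which select higher peaks. Lists above the upper percentile limit for coverage (16 of 23) numbered 2 at −log10 q of at least 5, 3 at a fold of at least 4 and 4 at q of at most 0.05, and 11 to 17 under the other alternatives. Of those at −log10 q of at least 5, 1 was also above in the full list. Where exon and assigned gene agree, CREB signalling (88.5), m6A-modified mRNAs, glycolysis, translation and EMT genes (67.5) were no longer above. With at least 5 fragments, CREB targets (73.2) and EMT genes were not, with all assigned peaks m6A-modified mRNAs, glycolysis and EMT genes (77.6), in unmatched lists CREB targets and stress response genes, and with the summit in the assigned transcript EMT genes. Lists above it for fold (1, CREB and CRTC targets) numbered 0 at q of at most 0.05, at a width of at most 1 kb, with all assigned peaks and with the summit in the assigned transcript. They numbered 2 in unmatched random lists, 4 matched on input level and 2 where exon and assigned gene agreed; the cause was not tested. No list had enough genes for a fold at −log10 q of at least 5. The count of 1 stayed at a fold of at least 4 and with at least 5 fragments or the median over each gene's peaks, but it was then the m6A list and, in the others, the chromatin regulators. Lists below the lower limit for fold (3) numbered 0 at q of at most 0.05 or matched on input level, and 5 with the median over each gene's peaks. Glycolysis was no longer below with all assigned peaks (36.2), nor the lenvatinib list with at least 5 fragments (31.3). Among 518 comparisons of single regions and lists, 303 stayed within their interval, 83 were higher and 132 lower. Of those that stayed, 44 with unmatched lists and 21 with lists matched on input level could not move. There only the random lists changed, not the value compared. The highest folds of CRTC2 and YTHDF2 and their medians differed by less than the counting intervals. Leaving out the mitochondrial genome and extra contigs moved none of the results it applied to. Motif density, distance to stop codons, the share of a peak that overlaps an exon and overlap with another annotation were not run. No paired analysis was possible because each group has 1 library.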

Other observations

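Of the tests in this part, those of joined sequence and of RIP coverage in wide peaks, of fragment numbers and widths in exon and intron peaks, of the share of peaks in chromatin regulators, and the choice of lists at q of at most 0.05 came after related values had been seen. In some transcripts a large share of exonic peaks was at q of at most 0.05; they are named because of these values. SETD1B, a histone methyltransferase gene, held them in 6 of 10 exonic peaks (60%, 26.2 to 87.8), JAG1, a Notch ligand gene, in 6 of 12 (50%, 21.1 to 78.9), the sorting nexin gene SNX4 in 5 of 11 (45.5%, 16.7 to 76.6) and TAF1 in 11 of 32 (34.4%, 18.6 to 53.2). Over all genes 2.67% of exonic peaks reached this q. The share was lower in the long transcripts of MACF1, 6 of 67 (8.96%), and KMT2C, 5 of 61 (8.20%).

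Of the 20 peaks with the highest −log10 q, 3 were annotated to exons or UTRs, 5 to intergenic sequence, 2 to introns and 10 to promoters, a class that can hold exons. Of these 20, 7 were wider than 10 kb. The strongest had a fold of 29.1 on 29 fragments at the FAM53A promoter (chromosome 4, 1684264 to 1688026). This peak was 3763 bp wide, at an input level of 0.0298, the floor. Neighbours of 30 fragments each lay at higher input levels. They were in intron 1 of FAM53A (10.7-fold, input level 1.90, 1680330 to 1680375) and in intron 4 of the adjacent histone mRNA binding protein gene SLBP (19.4-fold, input level 0.597, 1697166 to 1697212). Genes of ribosomal RNA held 75 peaks, of which 18 reached q of 0.05. Alternative and unplaced contigs held 0.648% of all peaks and 3.32% of those at q of at most 0.05.

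Zinc finger genes were tested as a family outside the fixed lists. Of 354 genes with a numbered ZNF symbol and an exonic peak, 22 (6.21%) had one at q of at most 0.05, against a random median of 10.2% (7.34 to 13.3) for genes with as many peaks, so the hypothesis of more peaks in zinc finger mRNAs failed, at percentile 0.32.

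Peaks wider than 10 kb numbered 16141 and reached 32.5 Mb, far beyond any transcript. At an input level below 0.0513 a base with 0 RIP fragments already has a Poisson p under 0.05, and among peaks with 1 fragment the median width was 1420.5 bp just below this level and 31 bp just above it, a ratio of 45.8. Of the wide peaks 92.8% lay below the level, against 1.03% of peaks up to 1 kb. Wide peaks had a median of 1 fragment at the summit against 2 in peaks up to 1 kb, so high RIP coverage did not mark them. A summit value does not measure breadth, so it cannot exclude broad coverage of low depth. Extra contigs held 2.12% of the wide peaks. A candidate explanation is that sequence without RIP fragments passed the limit and joined distant fragments, and the design gives no group to test a biological one.

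Exon peaks reached q of 0.05 more often than intron peaks. Wide intron peaks are argued against as the cause, because among peaks up to 1 kb the exon share minus the intron share was still 2.47 percentage points (2.32 to 2.62). Standardised to the fragment numbers of intron peaks with at least 3 fragments it was -7.36 points (-9.20 to -5.61). That value was fixed by the method, since p follows from fragments and input level and the median input level of these peaks was 0.634 in introns against 1.90 in exons. The numbers of peaks with enough fragments do bear on it. No peak with fewer than 3 fragments reached q of 0.05, and at least 3 were held by 36094 of 53302 exon peaks but 1443 of 46757 intron peaks. All 1590 exon and 174 intron peaks at this q were among these. Fragment numbers thus have a part in the difference. What gave exon summits more fragments was not tested, and neither was a biological explanation.

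Chromatin regulators held more peaks at q of at most 0.05 than random lists matched on length. A low median input level per gene is argued against. The list lay at percentile 100 of lists matched on it, and its median was 1.90 against 0.634 over all genes with a peak. This match cannot speak to the input level at the single peaks that reached this q, which was not tested. Matched on the number of exonic peaks the percentile was 77.7, and matched on both it was 85.0. Of their exonic peaks 36 of 871 (4.13%) reached this q, above the 2.67% of all genes and at percentile 78.6 of lists with as many peaks (random median 3.49%, 2.07 to 5.21). Many peaks per transcript may therefore account for the count, whatever brought them, and no biological explanation was tested.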
